A study of Mus musculus with 56 samples.

How the data were processed

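The data were bulk RNA-seq libraries of 7 sorted cell populations of mouse back skin, each from 4 zones in 2 biological replicates, 56 libraries in all. Per the labels' protocols, RNA was purified with a small-scale column kit, had an integrity number of at least 8.8, and entered amplification at 6 ng. Of the amplified cDNA, 100 ng went into each library, which was sequenced on an Illumina instrument. Whether the library kit kept strand, and the read length, are not given in the sources used here, so reads of a gene and its antisense partner cannot be separated here. The deposited values are RPKM per gene, reads scaled to gene length and library total, which the authors computed. The submitters' processing notes name the genome build mm10 and the tools STAR 2.4.0, featureCounts, limma, edgeR and DESeq2, with no version for the last 4. Filters applied before deposit are not given in the sources used here.

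The table holds 24062 gene symbols, used as given, with no coordinates. Of the genes above 0 in any library, 22217 of 22233 (99.9%) came out as whole multiples of the value of 1 read in all 56 libraries, within a tolerance of 0.02 reads, which gave the total each library was scaled to: 3.24 to 87.8 M reads, median 14.7 M. The recovered gene lengths equalled the exon union of GENCODE M21 for 9.52% of genes, so a different gene model stands behind the deposited values and no length was taken from the annotation. MicroRNA symbols (Mir genes) can take reads of host or overlapping transcripts in libraries of this kind, and Mira lies within the Hoxa cluster. Their values are uncertain, as are those of gene families with near-identical members (H2bc8, H2-M2, Akr1c18, Stfa3, Defb6, the Ces genes), where the counting could split reads. All columns were mapped to a sample by name. The 2 closest libraries of the series correlated at 0.9699, so none was a copy of another.

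All tests used limma 3.58.1 in R 4.3.3 (with statmod 1.5.0) on log2(RPKM + 1), over the 16731 genes with an RPKM of at least 1 in at least 2 libraries. A difference is on the log2(RPKM + 1) scale, which understates the change of low genes. One model with a mean for each of the 28 groups, 28 residual degrees of freedom and an abundance trend of the variance served every comparison. A population's mean over its 4 zones was compared between DP and DF, BuSC and HGSC, and Epi and Foll. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 and, in these comparisons, an absolute log2 difference of at least 1. Signature genes passed against each of the other 6 populations. Zones were tested within a population by the moderated F statistic, and direction was read from the linear trend over zones, with weights of 3 and 1 over 10, in log2 per zone step. Trend differences were tested as contrasts of these slopes. All tests were two-sided. The labels call the replicates biological, and n = 8 in a population stands for 4 zones with 2 replicates each, so p-values between populations measure the spread between replicates within zones.

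Of 49 gene lists of cell types, pathways and cell states, 45 had at least 5 tested members and entered camera with a preset inter-gene correlation of 0.01, over 10 contrasts (450 tests, adjusted within each contrast). Camera with an estimated correlation and fry, which tests whether a list moves one way and does not compare it with other genes, were run beside it. Of the 108 calls, 32 held with an estimated correlation, 8 of 19 between DP and DF, 10 of 28 between BuSC and HGSC, 6 of 17 between Epi and Foll, and in the zone trends 1 of 3 in DP, 1 of 4 in DF, 3 of 13 in BuSC, 0 of 6 in HGSC, 1 of 10 in Foll, 0 of 1 in Epi and 2 of 7 in Neg. In all 108 called lists the median, the mean and the test had the same sign. Merkel cell and red blood cell markers had too few tested members. Mitochondrially encoded genes matched 0 symbols of the table, and the Y-linked genes and Xist served only as a check of samples. Ligands and receptors among signature genes were tested by Fisher's exact test against all tested genes.

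Genes were named by a rule. It took the 3 label genes, and for each direction of a population comparison the 8 genes with the largest difference among those with the same sign in all 8 zone-by-replicate pairs and a mean RPKM of at least 10 in the higher population. It took 8 genes per signature by their smallest margin, 6 genes per direction and zone test by the zone 4 minus zone 1 difference and 4 per direction of a trend difference, with a mean RPKM of at least 5. It added up to 4 members per list, and left predicted genes and clones out of the parts on comparisons. Some genes that the rule takes are not reported here. Grouping, tests, lists, this rule and the other settings to be tried were set before the data were examined.

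The tests were tried on simulated data of 16218 genes. All genes and populations were drawn with a single dispersion, the spread between replicates beyond counting, taken from well-covered genes. Real spread differs between genes and populations, so the rates below need not hold for the real data. For DP against DF, 18 of 67 genes changed by a factor of 2 were recovered, 64 of 67 at a factor of 4 and 66 of 66 at a factor of 8, with 0 false calls among 15818 unchanged genes. For zones within DP, 20 of 100 genes with a slope of 0.5 log2 per zone and 97 of 100 with a slope of 1 were recovered, with 85 false calls among 15818. The other settings tried were a pseudocount of 0.1, no filter on low values, quantile and median-of-ratios scaling, array weights, a replicate block, each library and each zone left out, means over zones, other minimum differences, fits of the libraries compared alone, and a fit without Neg. Limma with voom on the recovered reads, and the omission of 6 doubted libraries together, of membrane-bound Wnt inhibitors from the ligands and of the genes behind the sort labels from the lists, were added after the data were seen. Figures were drawn with matplotlib 3.10.9, and tables prepared with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15.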

Results

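RNA was measured by sequencing in 7 cell populations sorted by fluorescence from the back skin of mice at postnatal day 22. The line carried green histone label under the keratin 14 promoter, green label at Crabp1 and red label at Lef1. DP denotes the dermal papilla, the mesenchymal signalling cluster at the base of the hair follicle, and DF dermal fibroblasts. BuSC denotes stem cells of the bulge and HGSC those of the hair germ, the epithelial stem cell pools of the follicle. Foll denotes other follicle cells, Epi the epidermis and Neg the unlabelled remainder, a mixed fraction. Each population came from 4 skin sections, called zones 1 to 4, in 2 biological replicates, which gave 28 groups and 56 libraries, 8 per population. The labels do not give the position of each zone, and their batch field holds the zone, so zone and batch cannot be told apart. They also do not say whether libraries with the same replicate number share animals. Depth ran from 3.24 M reads (Foll zone 4 replicate 2) to 87.8 M (Neg zone 3 replicate 2), with a median of 14.7 M. Across 16731 tested genes, the replicates of a group correlated at r = 0.841 to 0.951, a correlation across genes, which are not independent replicates. For 52 of the 56 libraries the closest other library belonged to the same population. Foll zone 1 replicate 2 was closest to a HGSC library. Replicate 2 of Foll zones 3 and 4 was closest to the same library, Epi zone 3 replicate 2, which was itself closest to a Foll library. It was the deepest Epi library, at 50.2 M reads. By mean correlation these libraries lay nearer their own population than any other (0.894 against 0.885, 0.897 against 0.892 and 0.914 against 0.895). Foll zone 1 replicate 2 did not (0.89 against 0.907).

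The genes behind the 3 labels were read first, in RPKM (mean ± SD, n = 8). Krt14, a keratin of basal epithelial cells, reached 1769.8 ± 439 in Epi, 1118 ± 180 in Foll, 501 ± 66.5 in BuSC and 415 ± 77.4 in HGSC, against 2.56 ± 1.39 in DP and 4.61 ± 3.32 in DF. Lef1, a transcription factor of the Wnt pathway, stood at 319 ± 24.3 in DP, 63.8 ± 9.29 in HGSC, 23.1 ± 12.4 in BuSC and 11.5 ± 3.37 in DF. Crabp1, which binds retinoic acid, reached 848 ± 284 in DP, 66.9 ± 19.1 in DF and 0.85 ± 0.676 in HGSC. Its BuSC level was 414 ± 337, with libraries between 134 and 1192. Neg, the unlabelled remainder, was not free of them, with Krt14 at 116 ± 41.1, Crabp1 at 59.1 ± 18.7 and Lef1 at 9.76 ± 3.48. These 3 genes helped to define the sort, so their differences check the sort and are not findings between populations.

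**Figure D1:**
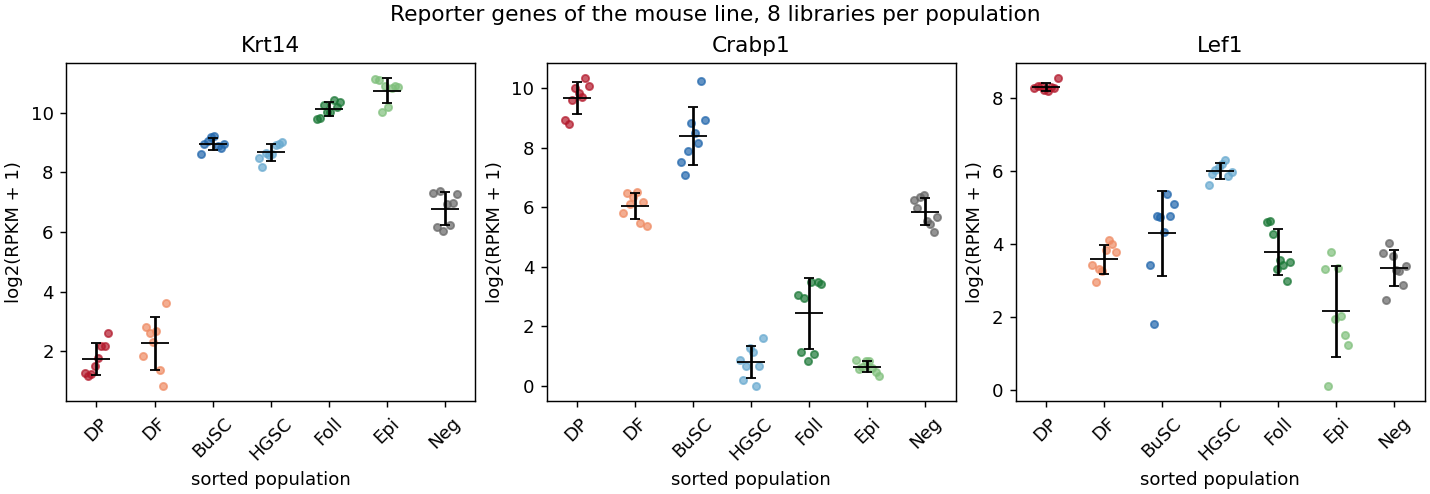
Levels of Krt14, Crabp1 and Lef1 as log2(RPKM + 1) on the vertical axis for the 7 sorted populations on the horizontal axis; points are libraries (8 per population) and the black marks are the mean ± SD of the log2 values. Krt14 was low in DP and DF, Lef1 was highest in DP (mean RPKM 319), and Crabp1 was high in DP and, with a wide spread, in BuSC (RPKM 134 to 1192).

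The comparison of DP with DF asked what sets the follicle's signalling mesenchyme apart from the surrounding dermis. DP expressed far more of several genes for secreted signals and of the prolactin receptor gene. The activin subunit gene Inhba stood at 1899.5 ± 263 RPKM in DP against 94.3 ± 31.2 in DF (log2 difference 4.36), and Bmp4 at 906 ± 71.4 against 60.8 ± 10.3 (3.89). Rspo3, which potentiates Wnt signalling, stood at 266 ± 42.9 against 9.65 ± 1.51 (log2 difference 4.65, SE 0.40, adjusted p = 6.1e-12), and the prolactin receptor Prlr at 295 ± 58.4 RPKM in DP (4.59, SE 0.17, adjusted p = 8.68e-21). DF expressed far more matrix and contractile genes. Examples were the proteoglycan genes Lum (898 ± 95.9 in DF, 5.49 ± 5.18 in DP; -7.42, SE 0.36, adjusted p = 4.06e-18) and Dcn (2614 ± 332 and 37.9 ± 28.7; -6.39). The collagen gene Col1a1 (21436 ± 2615 and 324 ± 74.8; -6.07) and the smooth muscle actin gene Acta2 (-6.54, SE 0.54) were likewise higher in DF. All values have n = 8. In all, limma called 5067 genes, 4042 higher in DP and 1025 higher in DF. Besides Rspo3, Prlr and the label gene Lef1 (4.72), the largest differences toward DP that held in all 8 zone-by-replicate pairs were those of the anion exchanger gene Slc26a7 (4.97), the transcription factor gene Sox18 (4.71), Cacng7 (4.71), Epn3 (4.66) and Pappa2 (4.56). Besides Lum, Acta2 and Dcn, those toward DF were Cpz (-6.85), Pcolce2 (-6.50), the smooth muscle myosin gene Myh11 (-6.41), Cd34 (-6.31) and Igfbp2 (-6.31).

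The balance of calls between DP and DF depended on scaling. The median of all genes lay 0.47 log2 higher in DP on the deposited values, and 0.09 and 0 higher after quantile and median-of-ratios scaling. The library factors of median-of-ratios scaling ran from 0.545 to 0.612 in DF and from 1.005 to 1.117 in DP, so abundant genes shifted by more than this median. Differences of single genes are given on the deposited values. The share of calls higher in DP was 79.8% on the deposited values, 44% (1363 of 3100) after quantile scaling and 33.6% (1053 of 3130) after median-of-ratios scaling. The 10 most abundant genes of DF took up to 42.3% of the reads recovered over all genes of a library, which are fewer than its total. List medians are therefore given below on the deposited values and then after median-of-ratios scaling, where the median of all genes is 0.

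Among gene lists fixed beforehand, 20 of 24 dermal papilla markers rose in DP and none fell (median log2 difference 3.87, then 3.02; camera adjusted p = 1.3e-13), led by Sox18, Rspo3, Prlr and Alx4 (4.45). Of 20 dermal fibroblast markers, 14 fell and 1 rose (median -3.01, then -3.91; adjusted p = 9.33e-18). Of 26 collagen and matrix genes 20 fell and 2 rose (-2.63, then -3.43; adjusted p = 3.56e-23), such as Lum, Dcn and Sparc (-5.86). Of 11 dermal sheath, smooth muscle and pericyte markers, 7 fell and 1 rose (-2.55, then -3.44; adjusted p = 1.16e-07), among them Acta2, Myh11, Des (-6.19) and Cnn1 (-5.98). Schwann cell markers fell in 6 of 10 cases (adjusted p = 3.61e-05), with Scn7a at -2.91. Of 16 chemokines 7 fell and 1 rose (adjusted p = 0.000103), with Ccl11 at -6.13 and Ccl7 at -3.94 against Cxcl14 at 2.68. Interferon response genes fell in 6 of 18 cases (adjusted p = 6.13e-05), with Ifit3 at -2.06 and Usp18 at -1.96. Of 28 basement membrane genes, 7 were higher and 8 lower (median -0.18, then -0.78; adjusted p = 0.00113, direction down), for example Lamc3 at 3.33 and Npnt at -4.08. After quantile and median-of-ratios scaling 5 were higher and 11 and 12 lower. In the fibroblast, matrix and smooth muscle lists no gene was higher after those scalings. These 8 lists also passed with a correlation estimated from the data. Where no count adjusted over the list alone is given, here and below, it equalled the count over all genes.

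Further lists passed with the preset correlation and not with an estimated one. Hair germ markers rose in 11 of 16 cases, Lef1 among them (adjusted p = 0.000103, and adjusted p = 0.000516 without Lef1; adjusted p = 0.12 with an estimated correlation). Wnt inhibitors, which restrain Wnt signalling, rose in 8 of 15 cases and fell in 1 (adjusted p = 0.0157; adjusted p = 0.134 with an estimated correlation), with Notum at 4.10, Sostdc1 at 3.91, Wif1 at 3.84 and Sfrp2 at 3.52. Of 5 FGF receptor genes, 4 rose and 1 fell (adjusted p = 0.027; adjusted p = 0.0787 with an estimated correlation), with Fgfr1 at 3.47 and Fgfr3 at 2.95. After median-of-ratios scaling 2 rose and 1 fell. Ribosomal protein genes rose in 14 of 20 cases (adjusted p = 1.64e-08; adjusted p = 0.134 with an estimated correlation), but in 3 after quantile scaling and in 0 after median-of-ratios scaling. Cholesterol synthesis genes rose in 12 of 17 cases (adjusted p = 0.00769; adjusted p = 0.108 with an estimated correlation), but in 4 and 3 after those scalings. Sqle stood at 2.30 and Hmgcs1 at 1.67. Immediate early and dissociation stress genes rose in 14 of 21 cases and fell in 1 (adjusted p = 0.001; adjusted p = 0.312 with an estimated correlation), and in 8 and 6 cases after those scalings. Socs3 stood at 2.96 and Egr3 at 2.65. The list test called neither the Wnt and R-spondin ligands (8 of 18 higher, adjusted p = 0.0743), nor the BMP, TGF-beta and activin ligands (9 of 14 higher and 1 lower, adjusted p = 0.0504), nor the Eph, plexin and Robo receptors (13 of 23 higher and 3 lower, adjusted p = 0.0504). After either other scaling the last 2 lists had 7 higher and 3 lower, and 8 higher and 4 lower. Single members of these and other pathways passed the gene test, such as Bmp7 at 4.43, Gdf10 at 4.43, Wnt10a at 3.98, Wnt6 at 3.94, Fgf10 at 4.38, the hedgehog receptor Ptch1 at 3.93, the hedgehog antagonist Hhip at 4.15 and the Notch target Hey1 at 3.52. The BMP antagonist Grem1 stood at 74 ± 19.6 RPKM in DF and 0.099 in DP (log2 difference -6.05, n = 8).

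The comparison of BuSC with HGSC asked how the stem cell pools of the follicle differ. HGSC expressed Shh, the hedgehog ligand, at 43.7 ± 12.8 RPKM against 0.492 ± 0.43 in BuSC (log2 difference -4.89, SE 0.28, adjusted p = 3.6e-15), the secreted protein gene Scube3 at 47.9 ± 10.2 against 1.5 (-4.42) and the iron exporter gene Slc40a1 at 76.2 ± 26.4 against 4.9 (-3.81). BuSC expressed the bulge marker Cd34 at 62.7 ± 27.3 RPKM against 0.368 ± 0.212 in HGSC (5.45, SE 0.18, adjusted p = 5.74e-22), the Wnt inhibitor Sfrp1 at 153 ± 39.1 against 11.2 (3.68) and Sox9 at 106 ± 19.7 against 22.4 ± 10.8 (2.29). The largest differences toward BuSC, Crabp1 aside (7.58), were in Coch (7.26, SE 0.31; 687 ± 638 RPKM against 3.45 ± 3.81), Kera (6.00), Fmod (5.77), Tnmd (5.52), Cd34, Prelp (5.09) and the complement inhibitor gene Serping1 (4.97). Coch, Kera, Fmod, Tnmd and Prelp encode matrix or tendon-type proteins. Toward HGSC they were Shh, Scube3, Defb6 (-4.13), the class II antigen presentation gene H2-Ab1 (-3.94), Slc40a1, H2-M2 (-3.58), Cyfip2 (-3.51) and Fa2h (-3.44). In all, 978 genes passed, 639 higher in BuSC and 339 higher in HGSC (n = 8 each). Voom on the recovered reads gave a count over 1.5 times as high.

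Bulge stem cell markers rose in BuSC in 11 of 20 cases (median 1.46; camera adjusted p = 2.37e-18), including Postn (4.30) and S100a4 (3.88). Dermal fibroblast markers rose in 16 of 20 cases (median 3.05; adjusted p = 1.33e-38). Collagen and matrix genes rose in 19 of 26 cases with 1 lower, 0 after either other scaling (adjusted p = 1.67e-29), with Col3a1 at 551 ± 498 against 20.3 RPKM (4.77), Col1a2 at 4.63 and Dcn at 4.35. Col1a1 stood at 750.4 ± 668 RPKM in BuSC against 32.7 in HGSC and 21436 in DF, and BuSC zone 4 replicate 1 reached 2356. Whether this fibroblast signal contributed to the other lists that rose in BuSC, the bulge markers among them, was not tested. Basement membrane genes rose in 6 of 28 cases and fell in 3 (adjusted p = 0.000146). FGF ligands rose in 3 of 9 (adjusted p = 0.000107), led by Fgf18 (2.09), Fgf1 (1.94) and Fgf7 (1.33). The PDGF, EGF, IGF and VEGF ligands rose in 4 of 23 (adjusted p = 0.0015), led by Igf2 (3.44) and Ccn2 (2.00). Hair shaft and inner root sheath genes fell in 5 of 10 cases (median -1.18; adjusted p = 4.33e-06), such as Krt35 (-2.75) and Krt28 (-2.45). Wnt target genes fell in 4 of 14 cases (adjusted p = 2.73e-05), with Tnfrsf19 at -2.14 and Myc at -1.44; the count includes the label gene Lef1, and the list passed without it (adjusted p = 0.000156). Cholesterol synthesis genes fell in 7 of 17 cases (8 adjusted over the list alone; adjusted p = 8.77e-11), such as Sqle (-1.55). Upper follicle and sebaceous markers fell in 6 of 15 (7 adjusted over the list alone; adjusted p = 2.93e-05). These 10 lists also passed with an estimated correlation.

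Hair germ markers were lower in BuSC in 7 of 16 cases (median -0.69; adjusted p = 8.4e-06; adjusted p = 0.0734 with an estimated correlation), led by Shh, Wnt10b (23.5 ± 13.2 RPKM in HGSC, 1.75 in BuSC; log2 difference -3.08) and Cux1 (-2.52). Melanocyte markers fell in 6 of 9 cases and rose in 1 (adjusted p = 0.00139; adjusted p = 0.116 with an estimated correlation), with Pmel at -1.68, Tyr at -1.65 and Mitf, which rose, at 1.53. Immune cell markers fell in 3 of 14 cases (4 adjusted over the list alone; adjusted p = 8.6e-05; adjusted p = 0.0592 with an estimated correlation), led by Cd74 (-3.32) and H2-Aa (-3.23). Interfollicular epidermis markers fell in 6 of 16 cases (7 adjusted over the list alone; adjusted p = 0.00124; adjusted p = 0.116 with an estimated correlation), with Krt77 at -3.23 and Krt1 at -2.74. Basal keratinocyte genes rose in 3 of 12 cases (adjusted p = 1.29e-05; adjusted p = 0.0605 with an estimated correlation, and adjusted p = 0.0423 without the label gene Krt14), with Col17a1 at 1.68, Dst at 1.40 and Krt5 at 1.06. Cell cycle genes gave 0 limma calls among 31 (1 at an unadjusted p under 0.05; camera adjusted p = 0.156). Of the ribosomal protein genes, 0 of 20 passed with the minimum difference and 19 had an unadjusted p under 0.05 (camera adjusted p = 7.87e-12, direction down; adjusted p = 0.0775 with an estimated correlation).

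The comparison of Epi with Foll asked what distinguishes the epidermis from the follicle cells outside the sorted stem cell pools. Epi expressed Wnt3 at 28.2 ± 13.2 RPKM against 6.26 ± 3.45 in Foll (log2 difference 2.04, SE 0.34, adjusted p = 5.39e-05), the interleukin 1 decoy receptor gene Il1r2 at 62 ± 21.7 against 16.7 ± 15.8 (2.24, adjusted p = 2.92e-05) and Serpinb10 at 17.8 ± 11.6 against 2.78 (2.53, adjusted p = 6.39e-06). Foll expressed the intermediate filament gene Vim at 52.8 ± 28.1 RPKM against 3.69 ± 1.81 in Epi (-3.48, SE 0.28, adjusted p = 1.37e-10), the secreted protein gene Fstl1 at 19.7 ± 5.8 against 2.3 ± 2.07 (-2.81) and the reductase gene Akr1c18 at 126 ± 60.3 against 20.6 ± 17.5 (-2.79). The other leading genes were Mir5623 (2.85), Cimip2a (2.28), Ucn2 (2.01), Il12rb2 (1.98) and Ces2f (1.97) toward Epi, and Alox15 (-3.34), Pdk4 (-3.29), H2bc8 (-2.92), Col3a1 (-2.80) and Calml3 (-2.79) toward Foll. In all, 1303 genes passed, 322 higher in Epi and 981 higher in Foll (n = 8 each). The share higher in Epi was 24.7%, against 42.5% (425 of 999) after quantile scaling and 38% (436 of 1147) after median-of-ratios scaling.

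Upper follicle and sebaceous markers were lower in Epi in 10 of 15 cases (median -1.48; camera adjusted p = 2.4e-10), among them Mc5r (-2.63), Mgst1 (110 ± 33.5 RPKM in Foll, 25.6 ± 18.6 in Epi; log2 difference -2.44) and the fat cell regulator Pparg (-2.42). Cell cycle genes were lower in 13 of 31 cases (median -0.86; adjusted p = 2.4e-10), such as Aurkb (-1.59) and Bub1b (-1.53), and in 8 and 10 cases after quantile and median-of-ratios scaling. Cholesterol synthesis genes fell in 7 of 17 (adjusted p = 7.47e-05), led by Insig1 (-2.28). Markers of other cell types moved with this comparison. Immune cell markers fell in Epi in 9 of 14 cases (10 adjusted over the list alone; adjusted p = 2.92e-06), with Tyrobp at -2.69. Endothelial markers fell in 5 of 11 (adjusted p = 1.48e-06), with Pecam1 at -2.57. Basal keratinocyte genes lay higher in Epi as a list, with 1 of 12 past the gene test and 3 and 4 after quantile and median-of-ratios scaling (median 0.70; adjusted p = 2.4e-10). Col17a1 stood at 587.5 ± 119.6 RPKM against 281 ± 65.6 (1.07). These 6 lists also passed with an estimated correlation. Collagen and matrix genes fell in 17 of 26 cases and rose in 2 (adjusted p = 2.4e-10; adjusted p = 0.0554 with an estimated correlation). Dermal fibroblast markers fell in 11 of 20 (with 1 more higher adjusted over the list alone; adjusted p = 1.19e-07; adjusted p = 0.0833 with an estimated correlation). Col1a1 stood at 20.7 RPKM in Epi and 155 ± 194 in Foll. Hair germ markers fell in 7 of 16 cases (adjusted p = 5.1e-05; adjusted p = 0.105 with an estimated correlation), with Hoxc13 at -1.66; the count includes Lef1, and the list passed without it (adjusted p = 0.000241). Interfollicular epidermis markers gave 0 limma calls of 16 on the deposited values (2 adjusted over the list alone, 5 at an unadjusted p under 0.05; camera adjusted p = 0.00233; adjusted p = 0.175 with an estimated correlation). After quantile scaling 3 were higher in Epi, and after median-of-ratios scaling 5. Krt10 stood at 1991 ± 331 RPKM in Epi and 1166 ± 704 in Foll (log2 difference 0.99, adjusted p = 0.0642). Epi against Foll gave 479 genes with only these 16 libraries in the fit, and 848 without zone 1.

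Signature genes were those higher in a population than in each of the 6 others, by at least 1 on the log2 scale. There were 531 in DP, 226 in DF, 48 in BuSC, 73 in HGSC, 76 in Foll, 157 in Epi and 750 in Neg. DP was led by Slc26a7 (362 ± 54.4 RPKM, next highest population 11.35), Rspo3, Pappa2, the sodium and chloride transporter gene Slc12a1, the protease gene Corin, Fgf10, Inhba and Gpc5. DF was led by Mir6546, Cib3 (33 ± 12.6, next 1.38), Adra1a, Miat, Mybpc1, Phex, the cholinesterase gene Bche (55.1 ± 7.81, next 5.81) and the phospholipase gene Pla2g2e. BuSC was led by the acetylcholine synthesis gene Chat (15 ± 14.3, next 0.528), Scrg1 (15.5 ± 5.5, next 0.919), Serpinb11, Il31ra (59.3 ± 19.9, next 10.2), Wfdc3, Fam163b, Sfrp1 (next 41.2) and Tnfrsf11b. HGSC was led by Shh (next 6.15), the arginase gene Arg2 (39.2 ± 9.78, next 7.01), Ascl4, the keratin genes Krt28 and Krt35, Slc40a1, Slc4a11 and Mtcl1. Foll was led by Akr1c18, Osgin1, Pdk4, the oxytocin receptor gene Oxtr (63.2 ± 14.7, next 15.5), the vasopressin receptor gene Avpr1a (167 ± 40, next 44.5), Ces1d, Aadacl3 and Psph. Epi was led by Mir5623, Mir466d, Wnt3, Il12rb2 (39.1 ± 11.4, next 10.1), Ces2f, Mir193b, Guca2a and Ccr4. Neg was led by the mast cell protease genes Mcpt4 (133 ± 57.4, next 1.16), Cpa3 (124 ± 48.6, next 1.44) and Cma1, the pericyte gene Rgs5 (271.5 ± 92.4, next 7.36), Gzmc, the T cell gene Cd3e (86.4 ± 24.3, next 4.03) and the lysozyme genes Lyz2 (380.2 ± 83, next 17.5) and Lyz1. Values are mean ± SD in RPKM (n = 8), and next is the mean of the next highest population. After quantile and median-of-ratios scaling the DF count was 577 and 691, and without the Neg libraries 539.

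**Figure D2:**
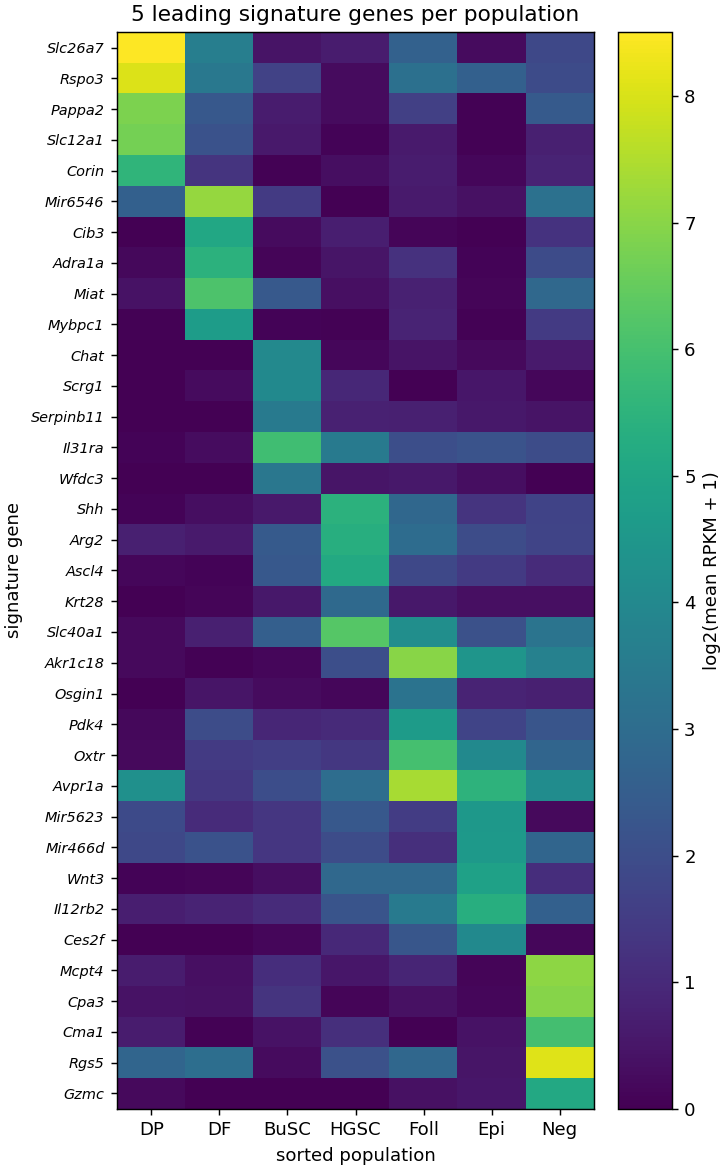
Heat map of log2(mean RPKM + 1), shown by colour, for the 5 leading signature genes of each population (vertical axis) in the 7 sorted populations (horizontal axis, mean of 8 libraries). Each block of genes is brightest in its own population, for example Slc26a7 in DP (mean 362 RPKM, next highest 11.35) and Mcpt4 in Neg (mean 133, next highest 1.16).

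Ligands, with the inhibitors and antagonists that act on them, and receptors were then counted among the signature genes, with Fisher's exact test over 138 ligand and 83 receptor genes, 14 tests in all. DP signature genes held 29 ligands where 4.38 were expected by chance (odds ratio 8.53, adjusted p = 5.02e-15), including the Wnt ligands Wnt5a, Wnt6 and Wnt10a, the R-spondins Rspo1 to Rspo4, Bmp4, Bmp7, Gdf10, Inhba, Fgf2, Fgf7, Fgf10, Igf1, Vegfa and the Wnt inhibitors Wif1, Sfrp2, Frzb, Dkk2 and Notum. BuSC signature genes held 4 ligands (0.4 expected, adjusted p = 0.00455), namely Ccn2, Sema3e, Sfrp1 and Tgfb3. HGSC signature genes held 4 (0.6 expected, adjusted p = 0.0137), namely Shh, Wnt7a, Wnt10b and Kremen2, the last a membrane co-receptor of Wnt inhibitors and not a ligand. Without the membrane-bound inhibitors Kremen1, Kremen2 and Apcdd1, a choice made after the data were seen, HGSC held 3 and lost the call (adjusted p = 0.0742). Neg signature genes held 10 receptors (3.72 expected, adjusted p = 0.0137), among them the vascular genes Flt1, Flt4, Acvrl1 and Eng and the mast cell and melanocyte receptor gene Kit. DP signature genes held 6 receptors, Dcc, Ednra, Epha7, Fgfr1, Tgfbr1 and Unc5c (adjusted p = 0.0892, not called).

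The zone comparisons asked whether a population differs along the skin sections. The moderated F test called 72 genes in DP, 33 in DF, 60 in BuSC, 23 in HGSC, 173 in Foll, 299 in Epi and 169 in Neg, each on 2 libraries per zone. The model behind it shared a single variance per gene over all 56 libraries. Replicates agreed less in Epi (r = 0.841 to 0.908) and Foll (0.862 to 0.899) than in DF (0.924 to 0.944). Zone p-values in Epi and Foll may therefore be too small. When the 8 libraries of a population were regrouped at random into 4 pairs, the median count was 41, 16, 22, 14, 130, 280 and 135 in the same order. Of 100 groupings, the labelled one included, 2, 1, 5, 8, 23, 41 and 6 reached the labelled count. Fitted on the 8 libraries of the population alone, the test called 1, 8, 2, 3, 15, 0 and 0 genes. Of these calls 2 in DF and 2 in Foll were among the genes called in the full model, and 0 in each other population. In the same limma fits 765 genes (Epi) and 1032 (Neg) had an unadjusted p under 0.05, where chance gives about 1 in 20 of the 16731 tested genes. On simulated data for zones within DP, drawn with a single dispersion for all genes, the test made 85 false calls among 15818 unchanged genes. It made 20 true calls of 100 genes with a slope of 0.5 log2 per zone and 97 of 100 with a slope of 1. Leaving out 6 doubted libraries, those closest to another population and a pair of BuSC libraries, gave 54, 35, 58, 34, 1172, 1227 and 141. Of all genes called, 748 passed in 1 population, 33 in 2, 1 in 3 and 3 in 4.

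**Figure D3:**
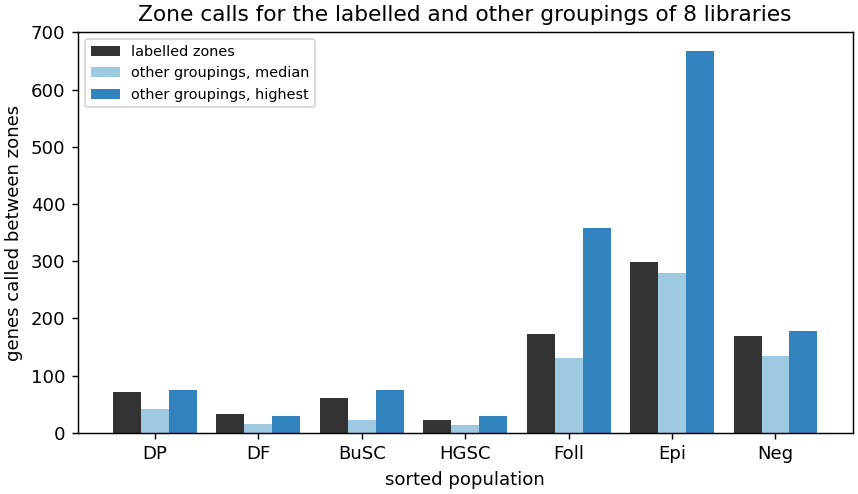
Number of genes called between zones (vertical axis) in each sorted population (horizontal axis), for the labelled zones (dark bars) and for other groupings of the same 8 libraries into 4 pairs (median, pale bars; highest, blue bars). The labelled zones exceeded the highest other grouping in DF (33 against 30), fell 3 short of it in DP (72 against 75), and lay near the median of the others in Epi (299 against 280).

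Hox genes, which mark position along the body axis, recurred across populations: of the genes called in 3 or 4 populations, chosen after their values were seen, Hoxc10 and Hoxa7 are Hox genes and Mira lies in the Hoxa cluster, and Gm53 is a predicted gene. Hoxc10 was at 0.0548, 0.448, 15.4 and 46.8 RPKM in zones 1 to 4 of DP (zone 4 minus zone 1 log2 5.49, SE 0.59, adjusted p = 6.18e-08; n = 2 per zone). It also rose in DF, from 0 to 34.3 (5.14, SE 0.59, adjusted p = 2.92e-06), and in Neg, from 0 to 35.4 (4.86, adjusted p = 6.25e-07). In BuSC it rose from 0 to 18.7 (3.63, adjusted p = 0.000997), the mean of 34.1 in zone 4 replicate 1, which also held the most Crabp1 and Col1a1 of the BuSC libraries, and 3.35 in replicate 2. Without replicate 1 of zone 4 the difference was 2.12 (adjusted p = 0.0657), and the call was also lost without the 6 doubted libraries (adjusted p = 0.105). Hoxc9 rose in DP from 0.323 to 13.9 (3.47, adjusted p = 0.00138) and differed between zones of DF, at 0, 4.55, 5.9 and 3.51 in zones 1 to 4 (zone 4 minus zone 1 2.05, adjusted p = 0.0416). Hoxa10 rose in DP to 5.89 (adjusted p = 0.000895) and in DF to 4.92 (adjusted p = 0.000185). In the epithelial populations, Hoxa7 rose in BuSC from 2.15 to 26.7 (3.40, adjusted p = 0.00885), in Foll from 1.47 to 21.5 (3.22, adjusted p = 0.0111; adjusted p = 0.126 without zone 1 replicate 1) and in Epi from 0.145 to 22.6 (4.35, adjusted p = 6.64e-05). Hoxd8 stood at 0.326, 8.45, 26 and 16.7 in zones 1 to 4 of HGSC (3.71, adjusted p = 0.0011). Here and below, rose and fell compare zone 4 with zone 1 for single genes. In counts of genes and in lists the direction is that of the linear trend over zones. Hoxb3 and Hoxd1, of the anterior groups, fell in DP from 14 to 1.83 (-2.41, adjusted p = 0.0159) and from 2.48 to 0.127 (-1.62, adjusted p = 0.0123).

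As a list, the 12 Hox genes of paralog groups 8 to 13 rose from zone 1 to zone 4 in each population. Gene calls were 4 in DP (camera adjusted p = 1.52e-09), 3 in DF (4 adjusted over the list alone; adjusted p = 2.25e-10), 2 in BuSC (7 higher and 1 lower adjusted over the list alone; adjusted p = 1.02e-08) and 1 in Neg (3 adjusted over the list alone, 2 called after median-of-ratios scaling; adjusted p = 2.88e-06), and these 4 list calls held with an estimated correlation. In BuSC the list call also held without zone 4 replicate 1, with 0 gene calls. Gene calls were 1 in HGSC (3 adjusted over the list alone; adjusted p = 0.00377), 0 by limma in Foll (2 adjusted over the list alone, 3 at an unadjusted p under 0.05; adjusted p = 0.00839) and 1 in Epi (2 adjusted over the list alone; adjusted p = 0.0323). These 3 list calls did not hold, at adjusted p = 0.0578, adjusted p = 0.087 and adjusted p = 0.147 with an estimated correlation. No list median of groups 8 to 13 changed sign under either other scaling. The 19 genes of groups 1 to 7 rose as a list in BuSC (1 gene call, 3 adjusted over the list alone; adjusted p = 0.00436), HGSC (0 limma calls, 3 adjusted over the list alone, 4 at an unadjusted p under 0.05; adjusted p = 0.0017), Foll (2 calls, 1 after either other scaling, 3 adjusted over the list alone; adjusted p = 0.00773) and Neg (0 limma calls, 3 at an unadjusted p under 0.05; adjusted p = 0.0154). These calls were lost, at adjusted p = 0.0803, adjusted p = 0.0829, adjusted p = 0.131 and adjusted p = 0.28 with an estimated correlation. Without Foll zone 1 replicate 1 neither Hox list was called in Foll (adjusted p = 0.0626 each). In Epi 3 genes of groups 1 to 7 rose (with 1 more lower adjusted over the list alone) and in DP 2 fell (3 adjusted over the list alone, 1 after either other scaling), without a call of the list (adjusted p = 0.0784 and adjusted p = 0.198).

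**Figure D4:**
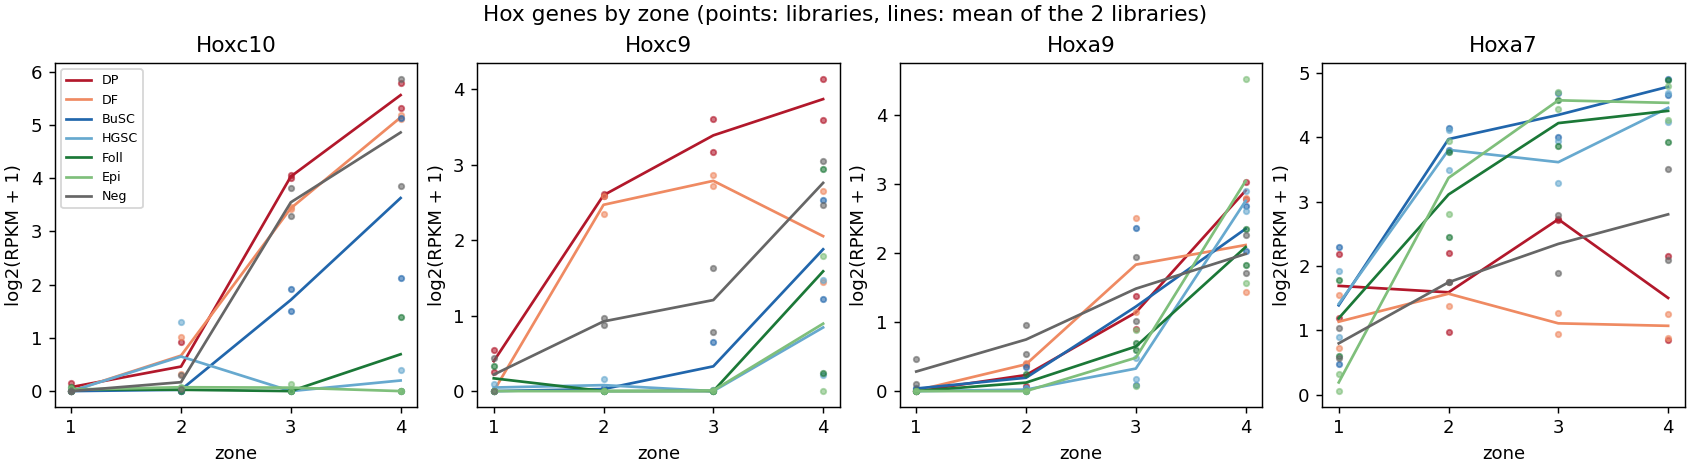
Levels of Hoxc10, Hoxc9, Hoxa9 and Hoxa7 as log2(RPKM + 1) on the vertical axis by zone on the horizontal axis, coloured by sorted population; points are libraries and lines join the means of the 2 libraries per zone. Hoxc10 rose from near 0 in zone 1 to 46.8 RPKM in zone 4 of DP and 34.3 in DF, and Hoxa7 reached 26.7 in BuSC and 22.6 in Epi.

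Other genes differed between zones within a population. In DP, Slc12a1 rose from 20 RPKM in zone 1 to 197 in zone 4 (3.24, adjusted p = 0.000347), the matrix gene Thbs1 from 5.43 to 23.5 (1.95, adjusted p = 5.28e-05) and Mir7022 by 3.91. The calcium-binding protein gene Pvalb fell from 12.3 to 1.44 (-2.44, SE 0.24, adjusted p = 1.64e-08) and Sncb from 14.9 to 1.7 (-2.25). Egfr rose in DP from 2.19 to 7.18 (1.47, adjusted p = 0.0264; adjusted p = 0.0993 without the doubted libraries). In DF, Cyp4b1 fell from 46.5 to 3.97 (-3.38, adjusted p = 0.000196). In BuSC, Clec11a rose from 1.57 to 30 (3.84, adjusted p = 0.00149), Wfdc3 from 0.327 to 17.5 (3.79, adjusted p = 0.000167) and Krt6a, a keratin of the companion layer, from 0.72 to 19.9 (3.59). Hhip fell from 17.7 to 2.18 (-2.62, adjusted p = 0.0388), a call lost after quantile scaling and without zone 4 replicate 2. Collagen and matrix genes had 0 limma calls of 26 (9 higher adjusted over the list alone, 16 at an unadjusted p under 0.05; camera adjusted p = 1.76e-18; adjusted p = 0.00983 with an estimated correlation) and were higher toward zone 4 in BuSC as a list. Dermal fibroblast markers had 0 limma calls of 20 (6 higher adjusted over the list alone, 10 at an unadjusted p under 0.05; camera adjusted p = 6.04e-11; adjusted p = 0.0551 with an estimated correlation). The BuSC library of zone 4 replicate 1 held Crabp1 at 1192 RPKM and Col1a1 at 2356, and without it the matrix list gave adjusted p = 1.44e-07 and adjusted p = 0.117 with an estimated correlation. The BMP, TGF-beta and activin ligands had 0 limma calls of 14 in BuSC (1 higher adjusted over the list alone, 3 at an unadjusted p under 0.05) and passed as a list (camera adjusted p = 0.00126; adjusted p = 0.00983 with an estimated correlation), but not without that library (adjusted p = 0.193). In HGSC, the growth factor binding gene Igfbp3 rose from 2.51 to 15.1 (2.37, adjusted p = 0.000266), Anxa1 from 22.8 to 77.7 (1.74, adjusted p = 0.0249) and Apoe from 183 to 450 (1.29, adjusted p = 0.0387). Quantile scaling gave 12 higher and 11 lower calls in HGSC, where the deposited values gave 16 and 7.

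In Foll, genes of the hair germ fell from zone 1 to zone 4, Shh from 13.8 to 0.295 RPKM (-3.33, SE 0.57, adjusted p = 0.0108), Msx2 from 21.4 to 2.89 (-3.04, adjusted p = 0.0325), the hedgehog effector gene Gli1 from 34.6 to 5.86 (-2.36, adjusted p = 0.0319) and Ptch1 from 115 to 25.2 (-2.15, adjusted p = 0.0263). Of 16 hair germ markers 5 fell (11 lower and 1 higher adjusted over the list alone; median -0.54 log2 per zone; camera adjusted p = 8.71e-15; adjusted p = 0.0125 with an estimated correlation), and 2 and 1 fell after quantile and median-of-ratios scaling. The zone 1 replicate 2 library of Foll was closest to a HGSC library, and without it 2 of the list genes passed, Msx2 and Gli1 lost the call (adjusted p = 0.0665 and adjusted p = 0.0627), and the list gave adjusted p = 2.4e-09 and adjusted p = 0.112 with an estimated correlation. Markers of another cell type fell along the same zones. Of 26 collagen and matrix genes 3 were lower (12 lower and 1 higher adjusted over the list alone; adjusted p = 0.000414; adjusted p = 0.344 with an estimated correlation), and of 20 dermal fibroblast markers 2 (3 adjusted over the list alone; adjusted p = 0.00232; adjusted p = 0.408 with an estimated correlation). Col1a1 stood at 629.6 RPKM in Foll zone 1 replicate 1 and between 43.7 and 149 in the other Foll libraries. Without that library the matrix and fibroblast lists gave 0 limma calls (adjusted p = 0.586 and adjusted p = 0.985), and 5 hair germ markers passed (list adjusted p = 5.94e-14; adjusted p = 0.0176 with an estimated correlation). Melanocyte markers, with 0 limma calls of 9 (2 at an unadjusted p under 0.05), and cell cycle genes, with 1 of 31 lower (2 adjusted over the list alone, 0 called after either other scaling), also fell as lists (adjusted p = 0.00391 and adjusted p = 4.34e-06; adjusted p = 0.27 and adjusted p = 0.131 with an estimated correlation). Without zone 1 replicate 1 both lists passed with an estimated correlation too (adjusted p = 0.0323 each), at medians of -0.57 and -0.37 log2 per zone. Without zone 1 replicate 2 neither was called (adjusted p = 0.662 and adjusted p = 0.0827), whereas the matrix and fibroblast lists were (adjusted p = 2.4e-09 and adjusted p = 1.8e-09), as were immune cell markers (adjusted p = 0.0072) and dermal sheath, smooth muscle and pericyte markers (adjusted p = 0.000618), each at adjusted p = 0.112 or adjusted p = 0.117 with an estimated correlation. Hedgehog pathway genes fell in 3 of 14 cases, and in 2 and 1 after those scalings (7 lower and 1 higher adjusted over the list alone; adjusted p = 0.00391; adjusted p = 0.131 with an estimated correlation). Mme (19 to 0.535, -3.69, adjusted p = 0.00186), Dlx3 (-3.61), Basp1 (-3.51), Srsf9 (-3.27) and Arg2 (-3.23) were the other leading genes that fell, and Stfa3 (1.32 to 63.6, 5.00, adjusted p = 0.0324), Mzb1 (3.23) and Mira (2.90) led those that rose. Dlx3 and Arg2 lost the call without the doubted libraries (adjusted p = 0.179 and adjusted p = 0.0949), and Stfa3 and Mira without zone 1 replicate 1 (adjusted p = 0.298 and adjusted p = 0.309). After quantile scaling 53 genes rose and 48 fell in Foll and 78 rose and 63 fell in Epi, and after median-of-ratios scaling 46 and 52 in Foll. On the deposited values 67 and 106 did in Foll and 211 and 88 in Epi. In Epi, where the 8 libraries fitted alone gave 0 calls, the peptidoglycan recognition gene Pglyrp4 rose from 0 to 31.2 (4.88, adjusted p = 6.64e-05 in the full model). Rab4b fell from 39.4 to 1.43 (-3.98, adjusted p = 0.00478), as did Nudt16 (21 to 0.0594, -4.27, adjusted p = 0.0209). In Neg, skeletal muscle markers rose in 2 of 6 cases (5 adjusted over the list alone; median 0.40 log2 per zone; adjusted p = 6.97e-09; adjusted p = 0.000134 with an estimated correlation), the troponin gene Tnnc2 from 0.213 to 16.1 (3.81, adjusted p = 0.00133) and the myosin light chain gene Mylpf from 1.38 to 11.3 (2.28, adjusted p = 0.00349). Cytl1 rose in Neg from 1.38 to 17.4 (3.11). The T cell gene Cd3d fell from 13.4 to 3.72 (-1.72, adjusted p = 0.0444), a call lost without the doubted libraries and with the replicate block.

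The last comparison tested whether zone trends differ between populations, as log2 per zone step. Between DP and DF 14 genes differed, 4 with a higher slope in DP and 10 with a lower one. Thbs1 (0.80, SE 0.12, adjusted p = 0.000888) and Smc4, which encodes a condensin subunit (-0.66, SE 0.14, adjusted p = 0.0318), were named by rule. The other genes with a higher slope, chosen after their values were seen, were Hapln1 (0.72), Prok2 (0.70) and 4930486L24Rik (0.51). After quantile scaling 27 genes passed, 12 higher and 15 lower, and after median-of-ratios scaling 27, 13 higher and 14 lower. Between HGSC and BuSC 3 genes differed: Serping1 (-1.43, SE 0.24, adjusted p = 0.00684) and, chosen after their values were seen, Wfdc3 (-1.25) and Ccdc87 (1.03). Each slope rests on 8 libraries, and with 1 library left out the counts ran from 12 to 36 and from 3 to 81.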

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

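Of the tests below, those fixed before their result was known were the omission of Foll zone 1 replicate 2, the HGSC signature genes in Foll, the count of replicates with a Hox trend and the regroupings of libraries; all other tests of explanations were chosen after the pattern was seen. For 2 of the latter, the source of the fibroblast list genes in BuSC and the head-to-tail order of the zones, the criterion was also revised once the value was known. Under the first wording the value counted against the first and for the second, and both are left undecided here.

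In BuSC, the dermal fibroblast and matrix genes and Crabp1 were high, with Crabp1 at 1192 RPKM in zone 4 replicate 1 against 485 in the next library. RNA of the DF cells is argued against as the source of Crabp1, since its mean in BuSC above HGSC was 626% of the DF level, and RNA of the DP cells is argued against by 138 genes abundant in DP, chosen without regard to BuSC, at a median of 1.4% and at most 29.3% of their DP level, where Crabp1 stood at 48.8%. A candidate explanation is a varying share of Crabp1-rich cells that carry fibroblast genes: over the 8 BuSC libraries, log2 Crabp1 and the mean log2 level of 27 called list genes (21 also at 1 RPKM or more in HGSC, 2 in another list) correlated at r = 0.89 (exact permutation p = 0.00603) and rho = 0.81 (exact permutation p = 0.0218), and r was 0.72 without the 2 libraries farthest from the median. Only 2 libraries lie in each zone, so the relation cannot be tested within zones. It was 1 of 5 relations of Crabp1 computed, the others with Coch, Kera, Tnmd and Fmod (r between 0.94 and 0.99), which were among the largest differences toward BuSC. Its p was the largest of the 5, so adjustment over the 5 could not change it (0.00603 for r and 0.0218 for rho, exact permutation). DF cells as the source of the list genes cannot be told apart from such cells, since the median was 10.3% of the DF level (quartiles 5.7 and 21.4%, Col1a1 at 3.35%, Dcn at 23.1%), too wide to decide, and no sort gate is described that would rule either out.

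In Foll, hair germ markers (16, all at 1 RPKM or more in Epi too and 11 in another list) fell from zone 1 to zone 4, at a mean of -0.53 log2 per zone; 3 of 26 matrix and 2 of 20 fibroblast genes fell too, 0 of either without zone 1 replicate 1 (limma), while without that library the hair germ mean was -0.60, that of melanocyte markers -0.65 and that of cell cycle genes -0.39. Foll zone 1 replicate 2, the library closest to a HGSC library, is argued against as the whole cause, since the mean was -0.46 without it, although called genes of the list went from 5 to 2. For the list as a whole, the same fall within hair germ cells is argued against by a mean of -0.03 in HGSC. Such a mean does not exclude a fall of single members. What stays open is a share of hair germ cells in the Foll sort, alone or with other cell types, that may decrease along the zones. Outside the list, 67 HGSC signature genes had a median of -0.32 in Foll, 58 of them negative and 8 called. These values include zone 1 replicate 2, the library closest to a HGSC library, so they cannot tell such a decrease from the effect of that library. The labels' batch field holds the zone, so a difference between batches cannot be told apart from such a decrease.

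Hox genes of paralog groups 8 to 13 rose from zone 1 to zone 4, with a positive mean trend in 14 of 14 series of a population and a replicate, which argues against a single replicate as the cause. RNA of DF cells in the HGSC, Foll, Epi and BuSC sorts is argued against, while DP and Neg were not tested. In zone 4 the list genes stood at a median of 79.5% of the DF level in HGSC, 44.7% in Foll and 25.5% in Epi, where Col1a1 stood at 0.1, 0.55 and 0.06%. They stood at 98.9% in BuSC, where Col1a1 stood at 7.2%. Foll and Epi pass narrowly, with lower quartiles of 2 and 0.2% and 6 of 8 genes at 3 times the Col1a1 share or more, and fibroblast-type cells other than DF stay open in BuSC. That the zone numbers follow the head-to-tail axis is a hypothesis that may account for the pattern but was not decided: 6 of 7 populations had a higher mean trend in groups 8 to 13 than in groups 1 to 7, and 4 of 7 by more than 0.05 log2 per zone. The biological difference between sections stays open as untested, since zone and batch coincide.

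Single libraries far from the other 7 of their population were looked for in 49 tests, of which 9 found one, where chance gives about 1 in 20, or 2.5. Genes at an RPKM of at least 1 numbered 10813 in DP zone 2 replicate 2 (next library 11357) and 10529 in Foll zone 4 replicate 1 (next 11308). Genes above 0 numbered 20248 in BuSC zone 2 replicate 2 (next 15702). The total was 30.1 M reads in HGSC zone 2 replicate 2 (next 15.7), 50.2 M in Epi zone 3 replicate 2 (next 13.4) and 87.8 M in Neg zone 3 replicate 2 (next 20.3). Lef1 was 373 RPKM in DP zone 4 replicate 2 (next 324). In BuSC zone 4 replicate 1, the 10 most abundant genes took 7.81% of the reads recovered over all genes (next 4.4%), besides the Crabp1 value of 1192 given above.

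Zone trends that differed between populations in a test of the difference itself numbered 14 for DP against DF, among them Thbs1 (0.80 log2 per zone) and Smc4 (-0.66), and 3 for HGSC against BuSC, among them Serping1 (-1.43).

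Each count of called genes was set beside 100 groupings of the same libraries, the real one included. Between populations only the real grouping reached its count (1 of 100 in each case, the smallest share possible). The populations were sorted apart beforehand, so this check could hardly come out otherwise, and it does not bear on single genes. In fits of the 16 libraries with a mean per population and no term for zone, DP against DF called 5099 genes with a highest other of 2846. BuSC against HGSC gave 851 and 167, and Epi against Foll 610 and 0. For signatures, in fits of all 56 libraries with a mean per population, the real value and highest other were 530 and 3 in DP, 228 and 0 in DF, 47 and 0 in BuSC, 72 and 0 in HGSC, 77 and 0 in Foll, 160 and 1 in Epi and 752 and 0 in Neg. For zones, the groupings were drawn in all 7 populations at once, so the variance shared over populations changed with them. Of these, 2 of 100 reached the count in DP (72 against 75) and 1 of 100 in DF (33 against 30), each under 0.05 alone. Adjusted over the 7 zone tests both shares were 0.07. With 100 groupings the smallest possible share is 0.01, so a lone population could not pass after this adjustment. Simulated zones within DP gave 85 false calls among 15818 unchanged genes, so chance is not excluded in DP or DF. Nor can it be excluded in BuSC (60 against 74, 5 groupings), HGSC (23 against 30, 8), Foll (173 against 358, 23), Epi (299 against 667, 41) or Neg (169 against 178, 6).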

How the results depend on the processing

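The omission of 6 doubted libraries, the voom fit and the omission of membrane-bound Wnt inhibitors from the ligands (3 of 4 calls held) and of the genes behind the sort labels from the lists (108 of 108 calls held) were chosen after the data were seen; the other settings were planned. Of 763 recomputed counts, 660 stayed within 1.5 times and 103 moved further; of 680 recomputed values of 170 named genes, 633 kept their call, 47 (of 35 genes) lost it and 0 reversed. Where fewer libraries, fewer or more genes or another minimum difference did not by construction account for a change, the cause was not tested. Counts of called genes follow. Fits that leave out a library leave 1 in its group, which is assumed to vary like the other groups.

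Without the 6 doubted libraries, zones gave 1172 in Foll and 1227 in Epi, and the HGSC against BuSC trends 13. Without Neg, signatures held 539 genes in DF and 75 in BuSC. Array weights gave zone counts of 116 (DP), 144 (DF), 71 (HGSC), 9 (Foll) and 20 (Epi), and 41 DP against DF trends. With an estimated correlation 32 of 108 list calls held. Voom gave 1603 for BuSC against HGSC, zone counts of 23 (DP), 238 (BuSC), 13 (HGSC), 41 (Foll), 125 (Epi) and 58 (Neg), and 2 DP against DF trends. With a minimum log2 difference of 2, signatures held 157 (DP), 53 (DF), 6 (BuSC), 12 (HGSC), 6 (Foll), 3 (Epi) and 280 (Neg). With none, the comparisons gave 8345 (DP against DF), 1858 (BuSC against HGSC) and 2717 (Epi against Foll). Median-of-ratios scaling gave 3130 for DP against DF, 691 in the DF signature, zone counts of 100 (DF), 10 (HGSC) and 98 (Foll), and 27 DP against DF trends. Quantile scaling gave 3100 for DP against DF, signatures of 577 (DF) and 498 (Neg), zone counts of 103 (DF), 39 (BuSC), 101 (Foll) and 141 (Epi), and 27 DP against DF trends. Without a filter, zone counts were 151 (DP), 94 (DF), 213 (BuSC), 61 (HGSC) and 407 (Neg), and trend differences 54 (DP against DF) and 24 (HGSC against BuSC). A pseudocount of 0.1 gave zone counts of 35 (BuSC), 450 (Epi) and 77 (Neg), and 6 DP against DF trends. With only the 16 libraries compared Epi against Foll gave 479. With only a population's 8 libraries zones gave 1, 8, 2, 3, 15, 0 and 0 in DP, DF, BuSC, HGSC, Foll, Epi and Neg. At an unadjusted p under 0.05 (limma) these fits gave 1005, 1193, 990, 1069, 865, 765 and 1032, where chance gives about 1 in 20 of the 16731 tested genes. Without zone 1, Epi against Foll gave 848 and the Epi signature 103.

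With each library left out in turn, counts ran from 4949 to 5187 (DP against DF), 921 to 1093 (BuSC against HGSC) and 1123 to 1561 (Epi against Foll). They ran for signatures from 519 to 544 (DP), 223 to 238 (DF), 46 to 61 (BuSC), 68 to 79 (HGSC), 70 to 88 (Foll), 118 to 196 (Epi) and 735 to 769 (Neg), for zones from 60 to 185 (DP), 29 to 54 (DF), 41 to 246 (BuSC), 18 to 73 (HGSC), 73 to 770 (Foll), 186 to 1130 (Epi) and 205 to 276 (Neg), and for trend differences from 12 to 36 (DP against DF) and 3 to 81 (HGSC against BuSC). Libraries that moved a zone count by over 1.5 times, written as zone and replicate, were in DP Z1_R1 (126) and Z2_R1 (185); in DF Z3_R1 (50) and Z4_R1 (54); in BuSC Z1_R1 (231), Z3_R1 (246) and Z4_R2 (203); in HGSC Z1_R1 (66), Z1_R2 (43), Z2_R2 (51), Z3_R1 (73), Z3_R2 (44) and Z4_R2 (36); in Foll Z1_R2 (282), Z2_R2 (424), Z3_R2 (419), Z4_R1 (73) and Z4_R2 (770); in Epi Z1_R2 (518), Z3_R1 (186), Z3_R2 (1130) and Z4_R2 (847); and in Neg Z3_R2 (276). For DP against DF trends they were DF Z4_R1 (24) and DP Z1_R1 (36), Z1_R2 (23), Z2_R1 (24) and Z4_R1 (31), and for HGSC against BuSC trends HGSC Z1_R1 (40), Z1_R2 (11), Z3_R1 (15), Z4_R1 (8) and Z4_R2 (13) and BuSC Z1_R1 (35), Z1_R2 (19), Z2_R2 (6), Z4_R1 (8) and Z4_R2 (81).

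Over 378 pairs of groups, deviations of same-numbered libraries correlated between -0.056 and 0.087, so no pairing effect was visible across genes. This cannot show whether animals or sequencing runs were shared. Depth did follow the replicate number in part: in zones 1 and 4, replicate 2 held fewer reads than replicate 1 in each population. With the replicate block, DP against DF gave 5074, BuSC against HGSC 977, Epi against Foll 1313. DP, DF, BuSC, HGSC, Foll and Epi signatures gave 531, 226, 48, 73, 76 and 159, Neg signature genes numbered 751, zones gave 72, 33, 61, 24, 184, 310 and 167, trend differences 13 and 4, and list calls 113. No count moved by over 1.5 times, and of the named genes Cd3d in Neg and Mir7681 in DP lost the call. Depth limits low genes most: 1 library held 3.24 M reads.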

Other observations

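The unlabelled fraction held markers of several cell types that the sort left over. Median levels over the lists, as log2(RPKM + 1), were 5.53 in Neg for 14 immune cell markers, against 2.08 in Foll, the next highest population. They were 5.15 for 9 melanocyte markers (next HGSC, 2.55), 4.60 for 11 endothelial markers (next BuSC, 1.13), 3.89 for 10 Schwann cell markers (next DF, 2.18) and 4.78 for 11 dermal sheath, smooth muscle and pericyte markers, where DF was higher at 5.36. List medians of fibroblast genes stood higher still in Neg, and on the deposited values they lay not far under those of DF. The library factors of median-of-ratios scaling ran from 0.977 to 1.103 in Neg and from 0.545 to 0.612 in DF. On that scaling DF would therefore lie further above Neg. The 20 dermal fibroblast markers were at 7.65 in Neg and 7.94 in DF, and the 26 collagen and matrix genes at 7.60 and 8.09. Col1a1 averaged 3634 RPKM in Neg and 21436 in DF. Mean RPKM (n = 8) in Neg was 227 for the melanin synthesis gene Dct, 68.2 for the endothelial gene Pecam1 and 26 for the leukocyte gene Ptprc. HGSC held Dct at 63.4 and BuSC at 27.2. Xist, transcribed from the inactive X chromosome, stood at means between 90.4 RPKM (DF) and 639 (Epi) in every population, and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had means of 0 in each population, except Ddx3y in HGSC (0.00365) and Neg (0.00307) and Uty in Neg (0.00242).

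Lists not described so far also differed between stem cell pools and between epithelia. BuSC had higher BMP and activin antagonists than HGSC in 3 of 11 cases (camera adjusted p = 0.0251; adjusted p = 0.105 with an estimated correlation), with Grem1 at 89.6 ± 25.9 against 6.07 RPKM (log2 difference 3.84) and Sostdc1 at 279.5 ± 81.8 against 102 (1.49; n = 8), and higher BMP target genes in 2 of 7 (adjusted p = 0.0261; adjusted p = 0.105 with an estimated correlation), Id4 at 1.89 and Smad9 at 1.40. FGF target genes were lower in BuSC than HGSC in 2 of 9 cases (adjusted p = 0.0158; adjusted p = 0.105 with an estimated correlation), Dusp6 at -1.88 and Spry1 at -1.69, and lower in Epi than Foll in 4 of 9, and in 2 after either other scaling (adjusted p = 0.00313; adjusted p = 0.0769 with an estimated correlation), with Dusp6 at -1.95. Circadian clock genes were higher in BuSC than HGSC in 3 of 16 cases and lower in 1 (adjusted p = 0.0146; adjusted p = 0.116 with an estimated correlation), with the clock repressor gene Nr1d1 at 88.1 against 25.9 RPKM (log2 difference 1.69). Between DP and DF the clock list was not called (adjusted p = 0.185), with 10 of 16 genes higher and 1 lower on the deposited values and 3 higher and 2 lower after either other scaling. Adipocyte markers, 2 of 6 lower in Epi than Foll (adjusted p = 0.0511), glycolysis genes, 2 of 13 higher and 1 lower in DP than DF, and 0 higher and 2 and 3 lower after quantile and median-of-ratios scaling (adjusted p = 0.495), Notch pathway genes, 8 of 16 higher in DP than DF (adjusted p = 0.102), and BMP, TGF-beta and activin receptors, 1 of 12 higher in BuSC than HGSC (adjusted p = 0.872), were not called as lists; the median of the receptor list changed sign with scaling, as did that of the glycolysis list. Counts adjusted over the list alone equalled those over all genes for these lists.

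Further lists passed with the preset correlation only. Between DP and DF these were cell cycle genes (2 of 31 higher and 5 lower in DP, 0 higher and 5 and 8 lower after quantile and median-of-ratios scaling, adjusted p = 0.00183; adjusted p = 0.202 with an estimated correlation), bulge stem cell markers (5 of 20 higher and 5 lower, 2 higher and 6 and 7 lower after those scalings, adjusted p = 0.0198; adjusted p = 0.12 with an estimated correlation) and, with 1 lower each on the deposited values, companion layer and inner bulge, skeletal muscle and melanocyte markers, the last with 2 and 3 lower after those scalings (adjusted p = 0.0299 each; adjusted p = 0.13, adjusted p = 0.108 and adjusted p = 0.295 with an estimated correlation). Between BuSC and HGSC, hedgehog pathway genes were higher in BuSC in 4 of 14 cases and lower in 2, 1 after either other scaling (adjusted p = 0.0421; adjusted p = 0.16 with an estimated correlation), with Gas1 at 2.92 and Hhip at 2.01. Ephrins and semaphorins were higher in 5 of 28 and lower in 1 (adjusted p = 0.0344; adjusted p = 0.0962 with an estimated correlation). Between Epi and Foll, Wnt receptors were lower in Epi in 3 of 18 cases and higher in 1 (adjusted p = 0.00834; adjusted p = 0.0833 with an estimated correlation), with Fzd7 at -1.68, and the PDGF, EGF, IGF and VEGF receptors were lower in 3 of 18 (adjusted p = 0.0412; adjusted p = 0.0833 with an estimated correlation). Dermal papilla markers were lower in Epi in 10 of 24 cases, and in 4 and 6 after quantile and median-of-ratios scaling (adjusted p = 0.000339; adjusted p = 0.105 with an estimated correlation). In the DP zone trends, ribosomal protein genes passed as a list (adjusted p = 0.00552; adjusted p = 0.909 with an estimated correlation) with 0 limma calls of 20 and 0 at an unadjusted p under 0.05. In Neg, cell cycle genes fell as a list (adjusted p = 4.59e-06; adjusted p = 0.28 with an estimated correlation) with 0 limma calls of 31 and 3 at an unadjusted p under 0.05.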
